A study of Mus musculus with 2 samples.

How the data were processed

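ELF1 ChIP-seq peak lists from the mouse cell line MEL were used, from 1 group of 2 biological replicates per the labels. The labels name a possible control experiment, which is not analysed here. Per the notes deposited with each sample, relaxed mm10 lists were called for each replicate and for the pooled replicates with a control alignment, and the optimal and conservative lists came from these through IDR with an exclusion list of regions. The mm9 list was derived from both replicates' mm9 alignments, per the same deposited notes. The aligner and the peak caller are not given in the sources used here. Each peak has a deposited signal value from the authors' peak caller, whose scale is not given, and it was used here only to describe and rank peaks within a list. The deposited score column of the IDR lists is a scaled IDR score of up to 1000, assigned by the authors. Median peak widths were 310 bp in the optimal list and in the mm9 list. Lists of 300000 peaks have a fixed length, so their number says nothing about depth, and no read counts were used, so depth per replicate is unknown.

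The reference sequence was mouse NCBIM37, the same as mm9, with GENCODE vM1 genes, and a table of RefSeq gene positions on GRCm38.p6, the same as mm10, served for the mm10 lists. On chromosome 1 the last mm9 peak ended at 196957981, within the reference length of 197195432. No coordinates were converted. The mm10 table gives 1 outer start per gene, and strand came from GENCODE by symbol or synonym. Of 21883 RefSeq protein-coding genes, 1203 had no clear strand and 126 lay in the leading gap of a chromosome, leaving 20554. For mm9, 45961 starts of protein-coding transcripts of 22359 genes were used, and the builds were joined by gene symbol. Promoter CpG and GC content came from the mm9 sequence within 500 bp of the start and were had for 20306 genes (98.8%).

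A gene was called bound if an optimal summit lay within 1000 bp of its start. Replicates were compared by overlap of at least 1 bp between their N best peaks by signal, with N = 20026, against 1000 random draws from the other relaxed list, and 100 draws for alternatives, or 50 where an overlap of 50% of both peaks was required. Settings without 1 replicate used the N best relaxed peaks of the other replicate, with no IDR step. Shares have 95% Wilson intervals. Counts were compared with two-sided Fisher's exact tests or the exact Cochran-Mantel-Haenszel test, with p kept down to 1e-300. Correlations across chromosomes and ranks across peaks used permutation tests with 100000 resamples. Families were adjusted by the Benjamini-Hochberg method at 0.05. Peaks and genes are not independent replicates, so these p-values describe these lists and not the spread between cultures.

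The tests, 24 gene lists, 11 motifs, the rule for named genes and most alternatives were fixed before the data were examined, and the alternatives added later are named in the closing section. The rule named the 10 strongest optimal peaks, for each list the 3 bound genes of highest promoter signal and up to 2 unbound genes first in the alphabet, any member of the erythroid, heme and iron, blood transcription factor and ETS lists, Elf1, and the strongest motif peak over 10000 bp from a start. Other genes are said to have been chosen after their values were seen. In the erythroid list 5 names, and in the interferon list 3, had no usable gene. The erythroid names were the beta-globin names Hbb-bs, Hbb-bt, Hbb-b1 and Hbb-b2, and Ahsp, so these genes were not tested.

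Several planned steps changed because no mm10 sequence was used here. Motifs were searched in the mm9 list instead of the optimal list, in 101 bp windows around the summit, and the background was the windows 500 bp to either side instead of relaxed peaks, in strata of 10 GC groups and promoter position. Summit and flank windows of the same peak were counted as separate windows, without using their pairing, and flanks took the promoter class of their peak. Motif tests with the conservative list, with single replicates and with the relaxed peaks ranked just below the optimal list were not run, nor was the motif share of unshared peaks. One gene-level start replaced transcript starts on mm10.

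The list tests, motif search, overlap and distance steps were tested on simulated data. Among 20000 simulated genes, lists with a true odds ratio of 2 were called in 26 of 50 cases (52.0%) and with 5 in 50 of 50, and lists without an effect in 2 of 100. Each simulated list was larger than the erythroid, blood transcription factor, ETS and megakaryocyte lists and was tested within strata. These shares therefore do not give the power for those smaller lists. The 95% interval held the true value in 192 of 200 lists. All 1000 planted motifs among 5000 sequences were found, and overlaps, distances and exact p-values matched direct counts or R in every simulated case. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, bedtools 2.31.1 and R 4.3.3 were used.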

Results

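ELF1 is a DNA-binding protein of the ETS family, whose members recognise a GGAA core and act in blood and many other cells. Its sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MEL, a mouse erythroleukaemia cell line held at an early red blood cell stage. The series has 1 group of 2 biological replicates, and the question the design poses is which regions hold ELF1 and how repeatable they are. The mm10 lists were an optimal list of 20026 peaks and a conservative list of 17799, both passed through the irreproducible discovery rate (IDR) procedure, and relaxed lists of 300000 peaks for each replicate and for the pool. A further list of 13595 peaks was given on mm9. The lists hold no read counts, so the sequencing depth of each replicate is unknown, and the intervals below cover counting of peaks or genes only.

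The strongest ELF1 peaks of the optimal mm10 list lay at protein-coding start sites, and both replicates held them. The strongest peak of the optimal list, with a signal of 497, was at Edem2, which helps clear misfolded glycoproteins from the endoplasmic reticulum. It was also the strongest peak of replicate 1 (signal 267) and of replicate 2 (signal 236). Next came Fam172a (457), Ciao3 (442), a factor of iron-sulfur protein assembly, and the promoter shared by Tatdn1 and the respiratory complex I gene Ndufb9 (431). Of the 20026 best peaks of replicate 1, 65.9% overlapped those of replicate 2, and 65.5% the other way, against 6.56% and 6.61% for peaks drawn at random from the other relaxed list (one-sided permutation p = 0.001 for each, the smallest that 1000 draws can give, n = 2 replicates). Each of the 1000 best peaks of either replicate overlapped the best peaks of the other, whereas at ranks 10001 to 20000 the shares were 42.6% and 42.1%. At 17860 optimal peaks (89.2%) with a relaxed peak in both replicates, the signals had a Spearman's rho of 0.70 (95% bootstrap interval 0.691 to 0.710), taken across peaks, which are not independent replicates.

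**Figure D1:**
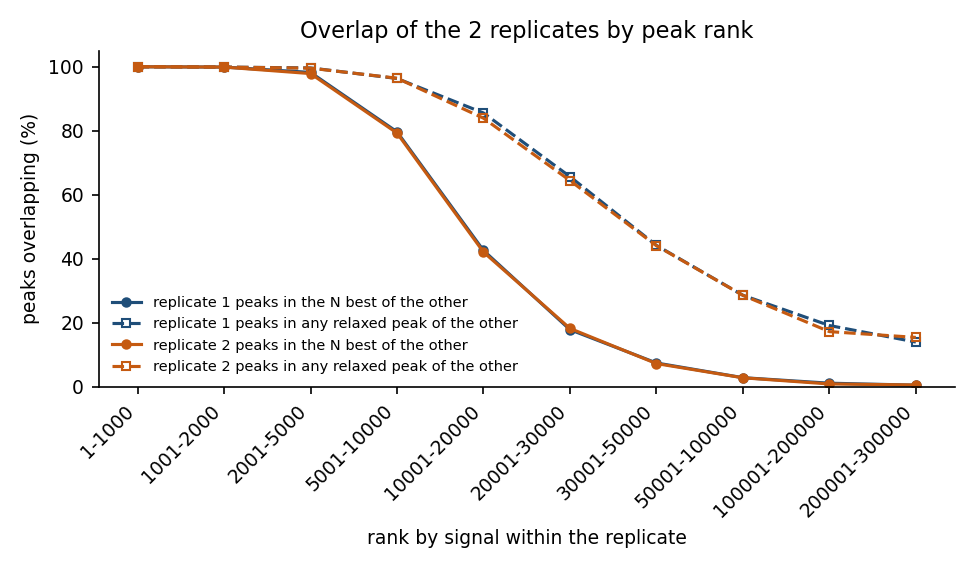
Share of each replicate's peaks (y axis, percent) that overlap the best 20026 peaks of the other replicate (solid lines, circles) or any of its 300000 relaxed peaks (dashed lines, squares), by rank of signal within the replicate (x axis). The lines of both replicates lie close together, at 100% for the 1000 best peaks and at 42.6% and 42.1% for ranks 10001 to 20000.

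Peaks that were not shared were weaker and less often at promoters. In replicate 1, 17.3% of the best 20026 peaks overlapped none of the 3N best of the other replicate (N = 20026), and 21.8% of these were within 1000 bp of a protein-coding start, against 42.0% of the others (odds ratio 0.386, two-sided Fisher's exact p = 2.82e-116). In replicate 2, 18.3% were unshared, with promoter shares of 16.0% and 40.2% (odds ratio 0.283, Fisher's exact p = 4.1e-186). The shares depend on the rule: 34.1% and 34.5% overlapped none of the N best peaks of the other replicate, and 8.21% and 9.03% none of its relaxed peaks. The 4785 optimal peaks that overlapped no conservative peak were likewise less often at promoters than the other 15241 (22.4% against 42.7%, odds ratio 0.388, Fisher's exact p = 4.13e-148), and their median signal was 19.04 against 40.6. The conservative list was not a subset of the optimal list, since 15217 of its peaks (85.5%) overlapped an optimal peak.

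Promoters held 37.8% of the optimal peaks (7575 peaks, 95% Wilson interval 37.2 to 38.5%), counting summits within 1000 bp of a protein-coding start. Among relaxed pooled peaks outside the optimal list the share was 4.52% (odds ratio 12.8, two-sided Fisher's exact p no larger than 1e-300, the smallest value kept). Gene bodies outside promoters held 34.5% of the optimal peaks and sequence outside genes 27.7%. Promoter peaks had a median distance of 95 bp to the start. When peaks were ranked by signal in 10 equal groups, the promoter share was 78.8% in the strongest group and 22.8% and 29.8% in the 2 weakest.

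The 10 strongest peaks, each with the highest possible IDR score of 1000, were within 55 bp of a protein-coding start (mm10 coordinates). Edem2 (chromosome 2, 155729303 to 155729609), Fam172a (chromosome 13, 77708511 to 77708843), Ciao3 (chromosome 17, 25773611 to 25773881) and Tatdn1 (chromosome 15, 58933638 to 58933905) were followed by Slc38a10, an amino acid transporter gene (chromosome 11, 120151140 to 120151461, signal 428). Atg7, whose enzyme starts autophagosome conjugation, had a signal of 421 (chromosome 6, 114642955 to 114643232), and Sirt7, a nucleolar deacylase gene, 418 (chromosome 11, 120624864 to 120625151). The others were Trmt44, a tRNA methyltransferase gene (chromosome 5, 35574946 to 35575228, signal 413), the ribosomal protein gene Rpl27 (chromosome 11, 101442146 to 101442450, signal 411) and Dbnl, which encodes an actin-binding adaptor (chromosome 11, 5788323 to 5788558, signal 406). In the mm9 list, 9 of these 10 genes also had a summit within 1000 bp of a start, and Atg7 did not.

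ELF1 was at the promoters of most genes for protein synthesis, RNA processing, protein breakdown and respiration. Of 20554 protein-coding genes, 6994 (34.0%, 95% Wilson interval 33.4 to 34.7%) had an optimal summit within 1000 bp of their outermost start and are called bound here. The share was 91.1% for spliceosome genes (41 of 45; odds ratio 19.98, adjusted p = 7.06e-15), 88.9% for tRNA synthetases (32 of 36; odds ratio 15.6, adjusted p = 4.08e-11), 84.6% for proteasome subunits (33 of 39; odds ratio 10.7, adjusted p = 2.68e-10) and 83.3% for cytosolic ribosomal proteins (65 of 78; odds ratio 9.77, adjusted p = 4.17e-18), by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 24 lists. It was 83.1% for oxidative phosphorylation genes (64 of 77), 82.1% for mitochondrial ribosomal proteins (64 of 78), 81.0% for RNA polymerase II and its general factors (64 of 79), 76.4% for translation initiation (42 of 55), 71.4% for DNA replication (30 of 42), 63.2% for autophagy and lysosome genes (24 of 38) and 48.5% for zinc finger proteins (174 of 359), each higher than among other genes (largest of these adjusted p = 0.000659, exact test). In all, 13 lists were higher and 7 lower than other genes. Of the 11 lists named in this paragraph, all but the zinc finger genes (1.93) had an odds ratio lower by more than 1.5 times within groups of promoters of like CpG content. They were 10.6 for spliceosome genes, 8.06 for tRNA synthetases, 7.09 for the proteasome, 4.51 for cytosolic and 4.12 for mitochondrial ribosomal proteins, 4.91 for oxidative phosphorylation, 3.98 for RNA polymerase II and its general factors, 2.96 for translation initiation and 2.31 for DNA replication. These calls were kept (largest adjusted p = 0.0289, exact test), and that for autophagy and lysosome genes was lost (odds ratio 1.90, adjusted exact p = 0.131). Without replicate 2 the odds ratio was 30.9 for tRNA synthetases, 9.07 for DNA replication and 5.08 for autophagy and lysosome genes, and without replicate 1 it was 13.3 for spliceosome genes, each a change of more than 1.5 times.

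Among ribosomal protein genes Rpl27 (signal 411), Rpl38 (338) and Rps27a (287) led, and Rpl13a had no optimal summit near its start in either build. Rpl13 had none in the optimal list and a peak in the mm9 list. Mrps33 (343), Mrpl50 (311) and Mrpl10 (268) led the mitochondrial ribosomal proteins, and Ndufb9 (431), Ndufa13 (386) and Uqcr10 (253) the respiratory chain. The splicing factor genes Sf3b5 (371), Prpf38b (274) and Snrpc (251) were bound, and Prpf40b was not. Gars (341), Dars2 (293) and Cars2 (221) led the tRNA synthetases, Psmd10 (322), Psmb3 (319) and Psmd9 (284) the proteasome, and Eif2s1 (312), Eif4ebp2 (260.9) and Eif2b1 (245) the initiation factors. Gtf2b (365), Gtf2f2 (340) and Taf2 (318), which help load RNA polymerase II, and the replication genes Gins3 (315), Cdc6 (279) and Cdc45 (260) were bound, whereas Cdt1, which licenses replication origins, was not. Atg7 (421), Map1lc3b (306) and Atg16l1 (291), which act in autophagosome formation, led their list, and Zfp513 (389), Zfp180 (381) and Zfp182 (361) the zinc finger genes. Psma6, Prpf3, Tars2, Fars2, Eif2ak4, Atp5d, Atp5g3 and Mrpl18 were not bound in the optimal list and were bound in the mm9 list, where all transcript starts counted. The strongest optimal summit in or within 10000 bp of Atp5g3 lay 1090 bp from its outer start. For Mrpl18 it lay at 1597 bp, for Atp5d at 2714 bp and for Psma6 at 14511 bp. Those of Eif2ak4 and Fars2 lay farther away, and Prpf3 and Tars2 had none. An unbound call in the optimal list can thus go with the starts used as well as with the peaks. More genes were bound in the mm10 list only (1539) than in the mm9 list only (890), and Eif2s1, Zfp513, Zfp180 and Atg7 were not bound in the mm9 list.

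**Figure D2:**
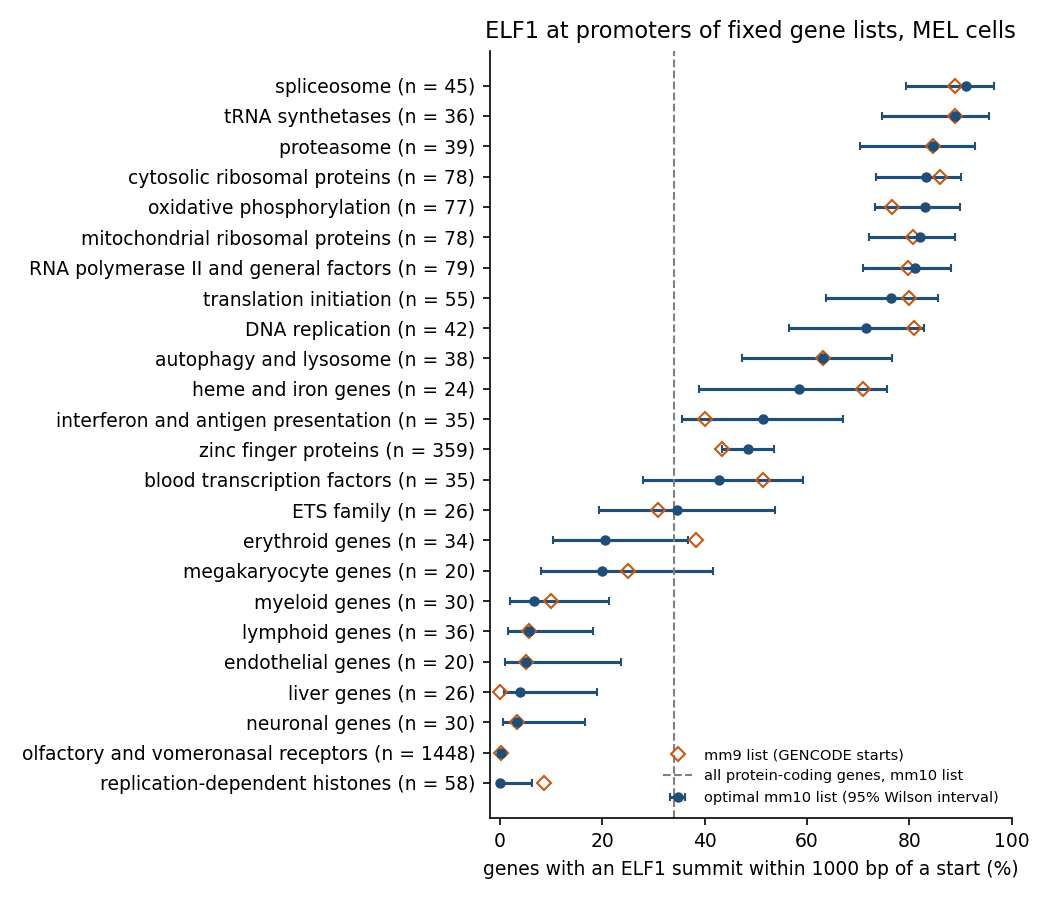
Percent of genes in each list with an ELF1 summit within 1000 bp of a start (x axis) for the optimal mm10 list (filled circles, bars are 95% Wilson intervals) and the mm9 list on transcript starts (open diamonds), with n genes per list. The dashed line is the share of all protein-coding genes in the optimal list, 34.0%. Lists for translation, splicing and respiration lie above 70% in the optimal list, and lists of other tissues at or below 20%.

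Genes of other tissues were rarely bound. In the optimal list ELF1 was at 3 of 1448 olfactory and vomeronasal receptors (0.207%; odds ratio 0.0036, adjusted exact p = 5.97e-265), 1 of 30 neuronal genes (Syp, signal 40.7), 1 of 26 liver genes (Apoa2, 53.3) and 1 of 20 endothelial genes (Icam2, 30.3). Lymphoid genes had 2 of 36, Ptprc (55.9) and Cd247 (30.9), and myeloid genes 2 of 30, Fcgr1 (30.5) and Cd68 (18.99). Among the bound genes named so far here, Apoa2, Cd247 and Cd68 were not bound in the mm9 list. These 6 lists were lower than other genes (adjusted exact p of 0.00514 or less), and with promoters of like CpG content compared by the exact Cochran-Mantel-Haenszel test, neuronal, endothelial and olfactory genes stayed lower (largest adjusted p = 0.0327). Lymphoid (odds ratio 0.499), myeloid (0.692) and liver genes (0.338) did not (adjusted exact p = 0.684, 1 and 0.638). The myeloid odds ratio of 0.138 was 0.226 without replicate 1 and 0.0622 without replicate 2, each a change of more than 1.5 times with the call kept. That call was also lost with a window of 5000 bp (odds ratio 0.847, adjusted exact p = 0.779), and the endothelial call in the mm9 list within CpG groups (0.141, p = 0.0542). Megakaryocyte genes, 4 of 20 bound and led by Pf4 (38.1), did not differ from other genes by the test (odds ratio 0.484, adjusted p = 0.262, exact test), and the direction turned within CpG groups (1.89, adjusted exact p = 0.377; in the mm9 list 3.19, p = 0.062). Without replicate 2 the odds ratio was 0.319 (adjusted exact p = 0.0675), a change of more than 1.5 times. Interferon and antigen presentation genes were bound more often (18 of 35, odds ratio 2.06, adjusted exact p = 0.0397), with Tbk1 (238), Ifnar1 (212) and Stat1 (154) the strongest. That call was lost in the mm9 list (odds ratio 1.49, adjusted exact p = 0.311), in the stronger 50% of peaks (1.45, p = 0.367), within GC groups (1.97, p = 0.0833) and among genes within 10000 bp of a relaxed peak (1.58, p = 0.243). It was kept within CpG groups (3.06, adjusted exact p = 0.0132), in the conservative list (3.96, p = 0.000138) and without replicate 1 (3.06, p = 0.00147) or replicate 2 (3.06, p = 0.0016).

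None of 58 replication-dependent histone genes was bound in the optimal list (95% Wilson upper bound 6.21%; adjusted Fisher's exact p = 1.36e-10). The relaxed pooled list, however, had no summit within 5000 bp of 55 of the 58 starts (94.8%), against 27.1% of all genes, so the mm10 lists say little about these clusters. In the mm9 list 5 of the 58 were bound (8.62%; odds ratio 0.211, 95% interval 0.0657 to 0.524, Fisher's exact p = 8.49e-05). The strongest was H3c7, chosen after its value was seen, with an mm9 signal of 728.

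Red cell genes were a mixed group. Of 24 heme and iron genes 14 were bound (58.3%, 95% Wilson interval 38.8 to 75.5%; odds ratio 2.72, adjusted exact p = 0.0209). They included Cpox (signal 114), Urod (52.1), Fech (48.9), Ppox (34.0) and Hmbs (26.4) of heme synthesis, the mitochondrial carriers Slc25a38 (77.4) and Abcb7 (59.9), and the transferrin receptor gene Tfrc (44.6). The erythroid synthase gene Alas2, its housekeeping relative Alas1 and the iron importer gene Slc25a37 had no promoter summit in either build, whereas Alad had none in the optimal list and a strong peak in the mm9 list (signal 809). The call for the list was lost with CpG-matched promoters (odds ratio 2.04, adjusted exact p = 0.177), within GC groups (2.14, p = 0.104), in the stronger 50% of peaks (1.39, p = 0.508) and among genes within 10000 bp of a relaxed peak (2.45, p = 0.0626). In the mm9 list 17 of the 24 were bound (odds ratio 5.45, adjusted exact p = 0.00012), and the call was kept there within CpG groups (4.70, p = 0.00235). Of 34 erythroid genes 7 were bound in the optimal list (20.6%, 95% Wilson interval 10.3 to 36.8%; odds ratio 0.502, adjusted exact p = 0.121), namely Bpgm (72.5), the membrane skeleton gene Epb41 (46.3), Trim10 (35.9), the red cell transcription factor gene Klf1 (35.2), Gypc (21.1), Hemgn (17.6) and Kel (16.7). Gypc and Kel were not bound in the mm9 list. The globin genes Hba-a1, Hba-a2, Hbb-bh1 and Hbb-y, and Slc4a1 and Spta1 of the red cell membrane, had no promoter summit in either build. The beta-globin genes Hbb-bs, Hbb-bt, Hbb-b1 and Hbb-b2 had no usable gene and were not tested. The erythroid odds ratio was 0.848 without replicate 1, 0.986 without replicate 2 and 0.858 in the conservative list, each a change of more than 1.5 times. Among the 32 erythroid genes within 10000 bp of a relaxed peak it was 0.392 (adjusted exact p = 0.0396). How far it lies below 1 thus depends on the peaks and genes used. The direction for this list turned in the mm9 list on transcript starts, where 13 of 34 were bound (odds ratio 1.39, adjusted exact p = 0.389; CpG-matched odds ratio 3.39, adjusted exact p = 0.0115). On outer starts, the kind used for mm10, 9 of the 34 were bound in the mm9 list (26.5%), so the turn may go with the starts.

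Of 35 blood transcription factor genes 15 were bound (42.9%; odds ratio 1.46, adjusted exact p = 0.299). The strongest promoter peaks were at Meis1 (signal 300), a homeobox gene of blood progenitors, E2f4 (275), a cell cycle regulator gene, Zbtb7a (165), Zfpm1 (142), which encodes the GATA1 cofactor FOG1, Foxo3 (109) and Etv6 (106). Max (72.3), Spi1 (58.9), Tcf3 (51.6), Lyl1 (38.6), Runx1 (24.1) and Tal1 (24.0) were weaker, and Tal1 was not bound in the mm9 list. Gata2, Myb, Myc, Lmo2, Gfi1b and Nfe2 had no promoter summit in either build, and Gata1 had none in the optimal list and a peak 126 bp from a start in the mm9 list (mm9 signal 64.8). Signals cannot be compared between the lists, and this peak ranked 8160 of 13595 in the mm9 list. Klf1 had a stronger peak 8055 bp from its start (149), Ldb1 a peak inside the gene (141), Gata2 a peak 4037 bp from its start (55.8), and Lmo2 a peak of 25.9 inside the gene. For these and the other optimal peaks named away from a gene's start, it was not checked whether the summit lies at another gene's start. They may thus belong to a neighbour. In the mm9 list 18 of the 35 were bound (odds ratio 2.37, adjusted exact p = 0.0188; within CpG groups 2.32, p = 0.062). The odds ratio was 2.15 without replicate 2 (adjusted exact p = 0.0369) and 1.53 without replicate 1 (p = 0.243).

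ELF1 was at the promoter of its own gene, with a signal of 35.4 at 523 bp from the outer start (chromosome 14, 79481542 to 79481851, mm10). Of 26 ETS family genes 9 were bound (34.6%, 95% Wilson interval 19.4 to 53.8%), close to the share of all genes (odds ratio 1.03, adjusted exact p = 1). Gabpa (signal 115), Etv6 (106), Elk4 (71.9), Spi1 (58.9), Etv3 (44.6), Erf (32.6), Etv5 (26.7) and Etv4 (26.4) were the other bound members, whereas Fli1, Erg, Ets1, Ets2 and Elf4 were not bound in either build. Etv5 and Etv4 were not bound in the mm9 list. Elf2 had no optimal summit at its outer start, a peak of 358 inside the gene, and a promoter peak in the mm9 list.

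Binding was more common at promoters rich in CpG, and genes with a divergent partner were more often called bound. Across 10 equal groups of genes by the ratio of observed to expected CpG around the start, the bound share was 3.05% in the lowest group and 58.1%, 59.5% and 58.4% in the 3 highest. Of 1757 genes with a divergent start of another gene within 1000 bp, such as Tatdn1 and Ndufb9, 74.2% were bound (95% Wilson interval 72.1 to 76.2%), against 30.3% of other genes (odds ratio 6.61, 95% interval 5.91 to 7.40, two-sided Fisher's exact p = 3.79e-284). Within CpG groups the odds ratio was 4.01 (3.55 to 4.55, exact Cochran-Mantel-Haenszel p = 1.25e-126). The rule for bound genes itself favours divergent genes, since a summit near the partner's start can count for both, as at Tatdn1 and Ndufb9. How much of the difference this makes was not tested. Partners that share a peak are not independent, so these intervals are likely too narrow and the p-values too small. Comparing genes within CpG groups removes neither problem.

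The ETS motif CCGGAAGY (Y is C or T) stood at the summits of the mm9 list, the list whose genome sequence was used. It lay within 50 bp of 14.1% of summits (95% Wilson interval 13.5 to 14.7%) and of 0.515% of windows 500 bp to either side, an odds ratio of 23.2 (95% interval 19.4 to 27.9) within classes of GC content and promoter position (two-sided exact Cochran-Mantel-Haenszel p no larger than 1e-300, the smallest value kept). None of 50 permuted 8-mers with the same bases and CG count reached that share (median 0.408%, highest 1.04%). The shorter MGGAAGY (M is A or C) was at 53.7% of summits against 5.83% of flanks (odds ratio 17.6), and the GGAA core at 92.3% against 65.0% (odds ratio 6.54). Promoter peaks had CCGGAAGY more often (23.4%) than peaks over 1000 bp from a start (5.61%; odds ratio 5.13, Fisher's exact p = 2.31e-203), and both exceeded their own flanks (odds ratios 25.4 and 17.8).

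Stronger peaks more often had the motif, which sat close to the summit. In the strongest of 10 equal groups 42.6% of peaks had CCGGAAGY and in the weakest 3.16%. The median mm9 signal was 170 with the motif and 69.8 without it (two-sided permutation test on ranks across peaks, p = 1e-05, the smallest that 100000 resamples can give). Among 2412 peaks with a match within 250 bp, the nearest lay a median of 19 bp from the summit and 52.7% lay within 20 bp. Matches per bp were 17.98 times as dense within 50 bp as from 150 to 250 bp, against 1.37 times for the permuted 8-mers.

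**Figure D3:**
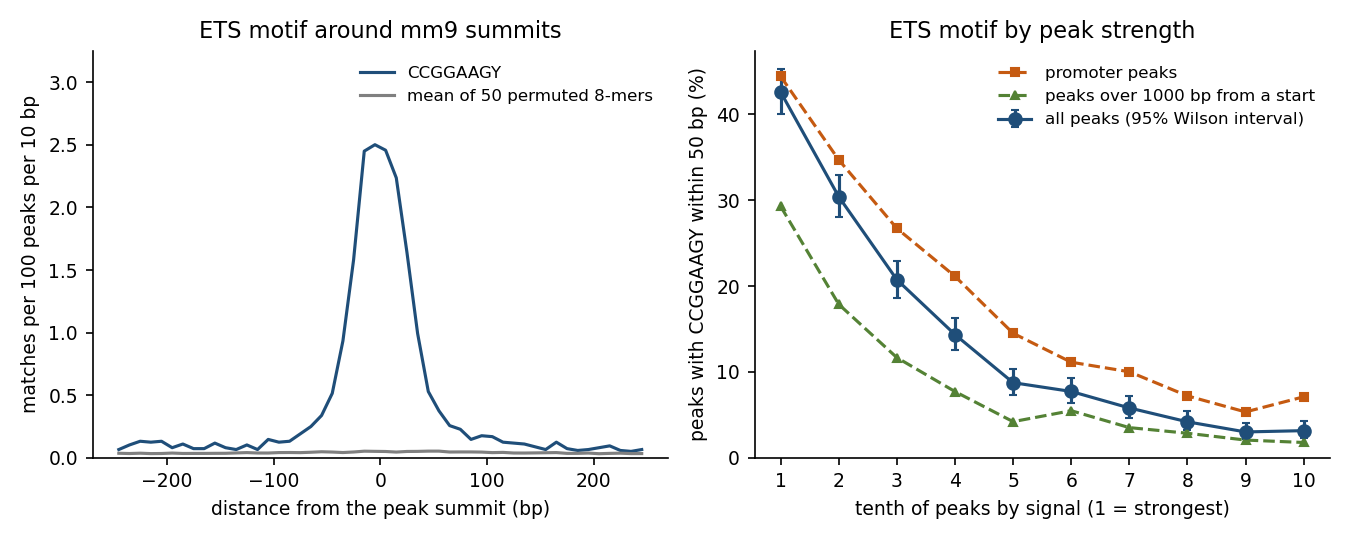
Left, matches to CCGGAAGY (blue) and the mean of 50 permuted 8-mers (grey) per 100 peaks per 10 bp (y axis) by distance from the mm9 summit in bp (x axis). Right, percent of peaks with CCGGAAGY within 50 bp (y axis) in 10 equal groups by signal (x axis, 1 is strongest) for all peaks (circles, bars are 95% Wilson intervals), promoter peaks (squares) and peaks over 1000 bp from a start (triangles). The share over all peaks is 42.6% in the strongest group and 3.16% in the weakest.

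Sites at the strongest genes are given on mm9, with 6 bases on each side of the match. At Fam172a the site was on the plus strand of chromosome 13, 77847970 to 77847977, in an untranslated exon, with the sequence GCAGACCCGGAAGTGCAATC. At Sirt7 it was on the minus strand of chromosome 11, 120486302 to 120486309, in an untranslated exon (CGGAAGCCGGAAGCGCAGTC), and at Slc38a10 on the plus strand of chromosome 11, 120012566 to 120012573, also in an untranslated exon (GGGAACCCGGAAGCGCCGCA). Outside annotated genes lay the site between Tatdn1 and Ndufb9 on the minus strand of chromosome 15, 58765339 to 58765346 (GGGAACCCGGAAGCGGGCGG), that of Trmt44 on the plus strand of chromosome 5, 35917728 to 35917735 (CGCGACCCGGAAGCGCATTG), and that of Dbnl on the minus strand of chromosome 11, 5688430 to 5688437 (AAGAGGCCGGAAGCGGAAGT), 1 of 2 matches within 50 bp of that summit. The summits at Edem2, Ciao3 and Rpl27 had no match within 50 bp. The strongest motif peak over 10000 bp from any start was nearest Rab3d, 16452 bp away (chromosome 9, 21705890 to 21706262, signal 1104, sequence CCATTACCGGAAGTTAGCGA). It lies in a stretch of chromosome 9, 20000001 to 23000000, picked for its crowded mm9 peaks, with 50.7 per Mb against a mean of 5.502.

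Motifs of other factors also lay near ELF1 summits, and they differed between promoters and other sites. All 11 motifs tested were more frequent within 50 bp of summits than in flanks (exact Cochran-Mantel-Haenszel tests, Benjamini-Hochberg adjusted over the motifs, largest adjusted p = 4.84e-05). The GATA motif WGATAR, bound by the red cell factor GATA1, was at 24.2% of summits against 13.97% of flanks (odds ratio 3.39). Away from promoters it was at 39.6% against 16.4% (odds ratio 4.45, 95% interval 4.14 to 4.79). At promoters the plain shares went the other way, 7.21% against 11.3%, and the odds ratio within GC classes was 1.43 (1.26 to 1.62). At promoters the CRE (odds ratio 15.4), NRF1 (9.003), CCAAT box (6.97) and THAP11/ZNF143 (29.5, from 55 peaks) motifs stood out, and away from promoters the core motif of the insulator protein CTCF (23.1, at 2.73% of peaks). Over all peaks the odds ratios were 8.97 for CRE, 8.50 for NRF1, 16.9 for CTCF, 30.8 for THAP11/ZNF143, 3.95 for the CCAAT box, 3.76 for YY1, 1.93 for the GC box, 1.84 for the E-box, 1.76 for AP-1 and 1.20 for RUNX. The string searched for THAP11/ZNF143 holds the GGAA core on its other strand, so its odds ratios are not independent of the ETS core. In each part 9 of the 11 calls were kept. That of THAP11/ZNF143 away from promoters rested on only 3 peaks, with a 95% interval from 0.844 without an upper bound. At promoters RUNX turned to 0.867 (adjusted exact p = 0.0931) and the AP-1 call was lost (1.12, p = 0.554). Away from promoters those of the GC box (1.29, adjusted exact p = 0.162) and YY1 (3.74, p = 0.138) were lost.

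**Figure D4:**
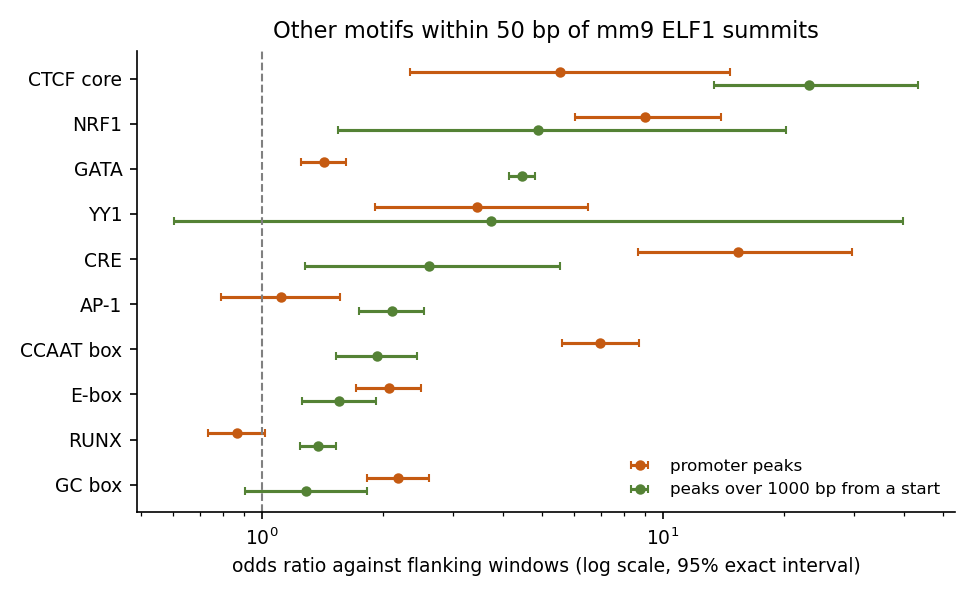
Odds ratio (x axis, log scale) of each motif (y axis) within 50 bp of mm9 ELF1 summits against flanking windows, within GC classes, for promoter peaks (orange) and peaks over 1000 bp from a start (green), with 95% exact intervals. THAP11/ZNF143 is left out because no flanking window away from promoters had it. GATA is 4.45 away from promoters and 1.43 at promoters.

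ELF1 peaks followed genes across chromosomes. Peaks per Mb and protein-coding genes per Mb had a Pearson's r of 0.81 (permutation p = 2e-05) and a Spearman's rho of 0.84 (permutation p = 2e-05) over 20 chromosomes, and r was 0.84 without chromosomes 7 and 11. Adjusted over the 2 relations tested, both p were 2e-05 by permutation. Chromosome 11 had the highest density (18.7 peaks per Mb) and 44.5% of its genes bound. The X chromosome had 2.51 peaks per Mb and 18.6% of its genes bound, below each of the 19 autosomes (8.18 ± 3.30 peaks per Mb and 35.0 ± 4.74% bound, SD over autosomes, lowest 4.80 and 27.0%). Relaxed pooled peaks were also fewest per Mb on X, 58.5 against 90.4 on the lowest autosome, chromosome 6. The low density of X is thus not particular to the optimal peaks, and its cause was not tested.

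**Figure D5:**
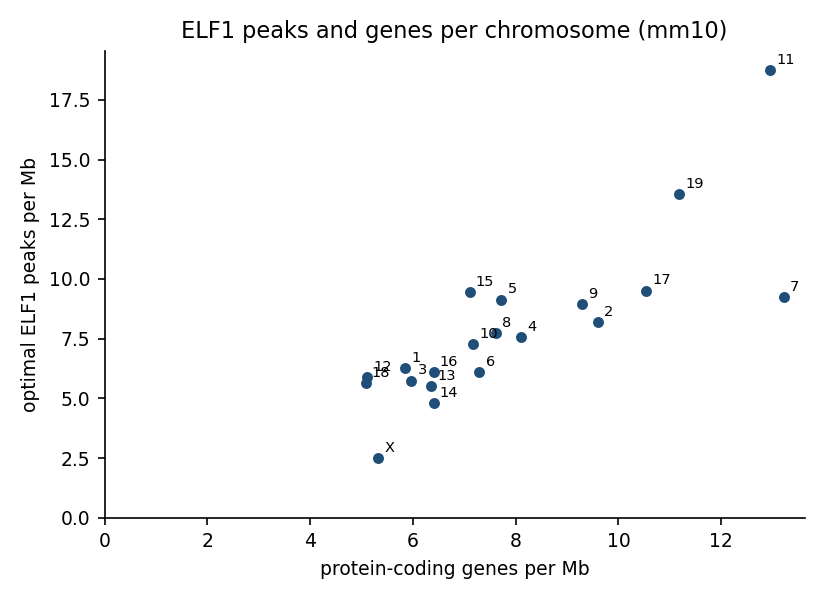
Optimal ELF1 peaks per Mb (y axis) against protein-coding genes per Mb (x axis) for 19 autosomes and the X chromosome (mm10), each point labelled with its chromosome. Chromosome 11 is highest at 18.7 peaks per Mb and X lowest at 2.51.

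The mm9 and mm10 lists named largely the same promoters. Of the genes tested, 6345 were bound in the mm9 list and 5455 in both lists, against 2159 if the lists were independent. The share of peaks per chromosome in the mm9 list had an r of 0.99 and a rho of 0.97 with that of the optimal list (permutation p = 1e-05 for each, the smallest that 100000 resamples can give; adjusted p = 2e-05 for r and 2e-05 for rho). Both lists come from the same replicates, so this is not independent evidence. Among mm9-bound genes, 132 had no relaxed mm10 summit within 5000 bp, among them Alad, the ribosomal protein gene Rps12, the survival factor gene Mcl1 and the proteasome gene Psmd4, the last 3 chosen after their values were seen.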

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

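The tests of gene density and extra copies for the stretch of chromosome 9, and both tests for the histone genes, were chosen only after the result was seen, and the others before. Peaks in sequence that no comparison used were found in the relaxed lists. On the mitochondrial genome replicate 1 had 14 peaks and replicate 2 had 0. On unplaced sequences there were 48 peaks in the pooled list, 47 in replicate 1 and 77 in replicate 2, each above the limit of 3 that a count of 0 allows, with no control sample to compare. The design has a single group, so no difference between conditions was weighed.

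Relaxed peaks were dense on chromosomes 11 and 15 even far from the protein-coding genes used, at 111 and 131 per Mb against 66.9 on the median autosome. That sequence lay over 10000 bp from any of these genes. Noncoding genes and the 1203 protein-coding genes without a clear strand were not masked. The densities, 1.66 and 1.95 times the median, leave out the optimal list and argue against the density of the genes used. The share of genes bound was 1.28 and 1.14 times the median. Although the first passed the limit set beforehand, bound promoters of the genes used cannot give peaks so far from their starts. That reading was made after the values were seen, and promoters of the unmasked genes were not weighed. Extra copies of the whole chromosomes are a candidate explanation that stays open, since 100% of the 10 Mb windows of chromosome 11 in both replicates, and at least 80% of those of chromosome 15, were above the median window. Copy number itself was not measured, and a larger share of open chromatin was not tested.

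The strongest peaks of the mm9 list were crowded in chromosome 9, 20000001 to 23000000, with 152 peaks (50.7 per Mb against a mean of 5.502) and 4 of the 10 strongest, near Tyk2, Pin1, Zfp809 and Fbxl12, genes chosen after their values were seen. The stretch was grown from the strongest mm9 peak over neighbouring 1 Mb bins with at least 5 times the mean count. Its crowding in the mm9 list is therefore built in. Peaks per gene were 3.10 times the autosomal value, which that choice also raises, so this value cannot decide on gene density. Relaxed peaks far from the protein-coding genes used were 3.86 times the median 1 Mb window in the lower replicate of the mm10 data. That passed the limit set for extra copies of the stretch after the result was seen. These peaks come from the same replicates as the peaks that picked the stretch. The choice can therefore raise this value too, and it cannot decide on extra copies, which stay possible. A missing control offset in the mm9 list cannot be told apart from extra copies, because the ratio of mm9 to mm10 signal in the stretch was 1.11 times that of other genes, between the limits of 1.1 and 1.5 set beforehand. The optimal mm10 list was also crowded across the genes of the stretch, with 79 peaks (36.4 per Mb against a mean of 7.96), and held 0 of its 10 and 3 of its 100 strongest peaks there, against 4 and 7 for the mm9 list. The mm10 lists lack part of the stretch: among autosomal genes bound on their outer start in the mm9 list, 20 of 47 in the stretch (42.6%) had no relaxed summit within 5000 bp, against 83 of 5806 elsewhere (1.43%; odds ratio 50.9, Fisher's exact p = 7.86e-24).

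No histone gene was bound in the mm10 list, and 2 explanations may both hold. The mm10 lists have no relaxed peak within 5000 bp of 94.8% of the histone starts, including all 5 that the mm9 list has as bound (H2bc9, H3c7, H2ac6, H2bc4 and H2ac21, chosen after their values were seen). In the mm9 list, which has peaks in these clusters, the odds ratio was 0.211, so fewer histone genes than other genes were bound there too.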

How the results depend on the processing

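Of 97 alternative values for results that answer a comparison, 91 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. Of 308 for single gene lists and motifs 271 did, 21 lost and 3 gained a call, 12 reversed, and the motif position moved to 1.37 for the permuted 8-mers by design. The settings with merged peaks, the mm9 list for genes, genes near a relaxed peak, promoter and distal splits of motif odds ratios, unbound starts as background and permuted 8-mers for motif position were chosen after seeing the data, and the others before. The optimal list has 10013 peaks in its stronger 50%. Rank correlation kept its direction but moved outside its interval, to 0.776 in the conservative list, 0.648 over all relaxed peaks and 0.719 with summits within 100 bp. Lists bound less often fell from 7 to 4 within CpG groups and to 3 in the mm9 list within CpG groups. The promoter odds ratio ranged from 5.79 at 5000 bp to 37.2 against peaks moved at random, and the ETS motif odds ratio from 6.54 for GGAA to 36.7 for MCCGGAAGT. Leaving out replicate 1 or 2 gave promoter shares of 35.8 to 38.5% and 6770 to 7322 bound genes, with 13 and 14 lists higher. The cause of the reversals was tested only for the erythroid list. Reversed lists were ETS family with an odds ratio of 0.813 at 500 bp, 0.890 within CpG groups, 0.709 within GC groups, 0.788 for genes near a relaxed peak, and 0.995 and 0.863 in the mm9 list without and within CpG groups. Megakaryocyte genes reversed to 1.89 within CpG groups and to 3.19 in the mm9 list within them, myeloid genes to 1.38 in the mm9 list within them, and RUNX to 0.867 at promoters. In the mm9 list erythroid genes reversed to 1.39, and to 3.39 within CpG groups; on outer starts their mm9 share was 26.5% instead of 38.2%. Among genes within 10000 bp of a relaxed peak, 32 erythroid genes were lower (odds ratio 0.392, adjusted exact p = 0.0396), and the histone call was lost with 4 genes left. No paired analysis between conditions was possible because there is 1 group. Summits and their own flanks could have been paired in the motif tests, but the pairing was not used. Planned motif alternatives that need mm10 sequence were not run. The distal THAP11/ZNF143 motif gave no finite odds ratio. Depth is unknown, so it cannot be said which weak peaks more reads would add.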

Other observations

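The distal and promoter motif comparison and the counts for the erythroid list were chosen after the data were seen, and the GATA test before. Between peaks of like GC content, the sites away from promoters and those at promoters carried different motifs. The GATA motif was more common away from promoters (odds ratio 3.10, 95% interval 2.75 to 3.50, exact p = 2.03e-84), as were the core motif of CTCF (11.1), AP-1 (2.78) and RUNX (1.89). The ETS motif (0.357), the CCAAT box (0.323), CRE (0.274), NRF1 (0.269), YY1 (0.167), the GC box (0.672) and THAP11/ZNF143 (0.0323) were more common at promoters (exact p of 0.00906 or less for each of these, not adjusted for several motifs), and the E-box did not differ by the test (0.898, exact p = 0.378). Exons outside promoters held 2.16% of mm9 peaks, introns 23.3% and sequence outside genes 26.9%, with CCGGAAGY at 10.9%, 3.73% and 6.81% of these.

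A hypothesis is that part of the ELF1 signal away from promoters may lie beside GATA sites. WGATAR was enriched at these summits over their own flanks with an odds ratio of 4.45, above the limit of 1.5 set beforehand. Of the other motifs with a finite odds ratio, only RUNX (1.38) and the GC box (1.29) were below 1.5 there. CTCF (23.1) and NRF1 (4.88) were above GATA. Passing the limit therefore does not single out GATA, and no open regions without ELF1 were compared. The test does not show whether ELF1 contacts the DNA itself at these places, where 5.61% of peaks had CCGGAAGY.

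The erythroid list differed between builds. Of its 34 genes, 8 were bound in the mm9 list only (Epor, Gata1, Gypa, Icam4, Ank1, Tmcc2, Cited2 and Cited4) and 2 in the mm10 list only (Gypc and Kel). The share bound was 38.2% in the mm9 list and 20.6% in the mm10 list. On outer starts, the kind used for mm10, 9 were bound in the mm9 list (26.5%), so the gap in shares narrowed on like starts. Of the 8 genes, however, only 3 were not bound on their outer start. In addition, 4 had an optimal summit in the gene or within 10000 bp, 3 had no relaxed mm10 summit within 5000 bp and 2 lay in the stretch of chromosome 9. None of these features covered all 8, and what sets the rest of the gap was left undecided.

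The 3 strongest mm9 peaks were among 24 wider than 500 bp. They lay near Tyk2 (signal 3754, 629 bp wide, 4103 bp from its start), Pin1 (2953, 602 bp wide, 396 bp away) and D19Wsu162e (2653, 645 bp wide, 270 bp away), genes chosen after their values were seen, and none of the 3 had CCGGAAGY within 50 bp of its summit.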
